A study of Homo sapiens with 8 samples.

How the data were processed

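CRTC2 is a cAMP-regulated coactivator that binds the transcription factor CREB. Chromatin immunoprecipitated with antibodies against it was measured on promoter microarrays (ChIP-on-chip). The cells were untreated Ramos cells, a Burkitt lymphoma line with features of germinal centre B cells. There were 2 antibodies against different parts of CRTC2 and 2 biological replicates for each, so 4 immunoprecipitations. Each was hybridised to 2 array designs that together tile the promoters (set 1 and set 2), which makes 8 arrays. On each array the immunoprecipitate carried Cy5 and total input chromatin carried Cy3, per the labels. No mock or IgG immunoprecipitation was among the samples.

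Per the file headers, the scanner intensity values were made with Agilent Feature Extraction 9.5.1.1. That software subtracted the background, put a surrogate value in place of each signal not above background, and normalised the dyes within each array by LOWESS with a smooth factor of 0.25. The deposited LogRatio column is the log10 of Cy5 over Cy3, per the file headers, and it was 0 at many spots with a surrogate. The authors also deposited a table with a z score of immunoprecipitate over input for each probe, whose scaling is not stated. The genome build of the probe positions is not given in the sources used here, so positions are printed as the files give them.

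The log2 ratio of the processed signals was taken for each probe and centred on the median of its array. Of 474411 probes that were not controls, 449869 were retained. Dropped were outlier spots and probes whose input was not well above background on all 4 arrays of the design. A window was a retained probe with the mean of all retained probes within 500 bp, and needed at least 3 probes, which gave 397866 windows with a median of 5 probes. A promoter value was the mean of the retained probes within 1 kb of a gene start, again with at least 3 probes, which gave 16540 genes with a median of 8 probes. A gene with more than 1 annotated start, such as CREM or BCL6, therefore covers more than 1 stretch. Of 17690 gene names in the files, 16292 were matched to a current symbol through their RefSeq accession in the table given, and 3988 symbols changed.

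Where the immunoprecipitate signal is a surrogate, the spot was not above background and its ratio is an upper limit. Surrogates were kept, and their share is given for the named promoters at which it was highest.

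Windows and promoters were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with 1 coefficient per antibody. The contrasts were the mean of both antibodies, each antibody, and antibody 1 minus antibody 2. Tests were two-sided with Benjamini-Hochberg adjustment. A window or promoter was called enriched, or depleted, at an adjusted p under 0.05 and at least 1.5-fold (0.58 on the log2 scale). Errors are SDs over the 4 immunoprecipitations. Depleted counts were taken at the same limits as enriched counts, since no mock immunoprecipitation gives a background. As a ratio centred on the array median, an enrichment is relative to the other probes of the array. The number of arrays limits the precision.

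The 4 immunoprecipitations came from 2 runs, per the scan runs in the file headers. Replicate 1 of both antibodies formed run 1 and replicate 2 formed run 2, except that the set 2 array of antibody 2 replicate 1 was scanned apart from the others. Over promoters, the deviations of same-numbered replicates from their antibody's mean correlated at r = 0.936 across genes. Values with the replicate as a block, and within each run, therefore stand beside the results. Both take the run difference out of the error. Against input, their p values and counts therefore do not measure the spread between replicates. The main fit counts the 4 immunoprecipitations as independent, although the antibodies share the run difference. For the mean of both antibodies its error is therefore too small, and its p values and counts against input are too optimistic. The SDs over 4 likewise do not stand for 4 independent values.

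There were 14 gene lists: CREB and CRTC target genes, germinal centre B cell genes, plasma cell genes, DNA repair and damage response genes, cAMP and CRTC2 pathway genes, cytosolic ribosomal protein genes, mitochondrial respiratory chain genes, replication dependent histone genes, cell cycle genes, marker genes of T cells, hepatocytes, neurons and skeletal muscle, and olfactory receptor genes. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A list's shift is its median minus the median of all promoters. Lists, thresholds and the rule for named genes were fixed before the data were examined. The rule named the 15 highest promoters among those enriched and above 0 in all 4 immunoprecipitations, and the 5 genes with the smallest p each way between antibodies if none was called. It also named up to 4 called members per list, or the highest member where none was called, 12 genes whatever their value (11 of which are given), and the 5 highest regions of called windows. A region joined consecutive called windows with gaps of at most 1000 bp, and single called windows were not counted as regions.

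The test was tried on simulated data for the 16540 promoters, with 66 or 67 genes changed per size and the rest unchanged. In the data, limma gave 9654 promoters an unadjusted p under 0.05. Recovery depends on how many genes are changed, so the shares below do not give the recovery in the data. Of genes given a log2 value of 1.2, 68.7% were recovered when the noise carried the run difference of the data, and 76.1% with the replicate block. At 0.8 the unblocked share was 23.9% and the blocked 58.2%, and at 1.6 they were 84.8% and 86.4%. Of unchanged genes, 0.0367% had an unadjusted p under 0.05 without the block and 6.70% with it. The simulated run difference was equal and opposite in the 2 runs, so it cancelled in the tested mean. The low share without the block therefore followed from this setting and does not show that the test guards against a run difference. With independent noise the unblocked shares at 0.8, 1.2 and 1.6 were 34.3%, 61.2% and 71.2%, whereas limma with the block recovered 0% at each size. Unchanged genes at an unadjusted p under 0.05 then made up 5.87% without the block and 6.18% with it.

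Alternatives fixed in advance were normexp background correction with an offset of 50, loess within arrays, equal spread, no filter on dim probes, narrower windows of 250 bp and promoters of 500 bp, single probes, other size and p limits, the replicate block, separate fits per design, leaving out each immunoprecipitation, and the z scores. Alternatives chosen after seeing the data were leaving out probes with a surrogate, the LogRatio column, a correction for probe length, centring on the median promoter, each run alone, leaving out chromosomes X and Y, and exchanging the labels of antibody 1 replicate 2 and antibody 2 replicate 1 as the z columns pair with the arrays. The CRE motif search and the correction for GC content were not run, since neither probe sequences nor a genome were available. Other tools were the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), Python 3.11.15 and matplotlib 3.10.9.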

Results

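Chromatin immunoprecipitated from untreated Ramos cells with 2 antibodies against CRTC2, 2 replicates each, was measured on 8 arrays. These carried 237210 probes in set 1 and 237201 in set 2. The input signal was well above background at 95.2% to 99.4% of the spots of an array, and the immunoprecipitate signal at 58.7% to 73.2%. Surrogates stood in for the immunoprecipitate at 26.7% to 41.2% of spots. Median signals were 493 to 1179 for the input and 273 to 1127 for the immunoprecipitate. The SD of the log2 ratios was 0.78 to 0.87 on the arrays of replicate 1 and 1.13 to 1.18 on those of replicate 2.

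The first comparison, immunoprecipitate against input over both antibodies, asks which promoters the CRTC2 antibodies enriched relative to the other probes. Without a mock immunoprecipitation it cannot tell binding of CRTC2 from other sources of a high ratio. Of 16540 promoters, 2457 (14.9%) were enriched and 1238 (7.48%) were depleted past the same limits. The fit took the 4 immunoprecipitations as independent although the antibodies share the run difference, so these counts and their p values are too optimistic. Depleted promoters outnumbered enriched ones when values were centred on the median promoter (2077 against 532), in run 1 alone (886 against 675) and at a 2-fold limit (380 against 108). The highest value was at ADPRH, a hydrolase that removes ADP-ribose from arginine, with a mean log2 ratio of 1.56 ± 0.38 (SD, n = 4). FIG4, a phosphoinositide phosphatase, stood at 1.53 ± 0.32, and MXD4, a MAX partner that opposes MYC, at 1.31 ± 0.46. The depleted side was led among the lists by olfactory receptor genes, which encode odorant receptors of the nose, with 154 of 268 depleted.

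Among the 15 highest promoters, ADPRH was covered by 4 probes at chromosome 3, 120780705 to 120782192, and FIG4 (KIAA0274 in the files) by 4 probes at chromosome 6, 110119177 to 110119831. MXD4 had 7 probes at chromosome 4, 2230039 to 2231782. The zinc finger genes in this group were ZNF33B at 1.44 ± 0.23, ZNF184 at 1.28 ± 0.42 and ZNF678 at 1.24 ± 0.08. PABIR2 stood at 1.48 ± 0.29, the microRNA gene hsa-mir-191 at 1.42 ± 0.53 and PRELID3A at 1.34 ± 0.27. MON1A, which acts in endosomal trafficking, reached 1.33 ± 0.46. RPP14, a ribonuclease P subunit, reached 1.31 ± 0.38, and H2AC15, a histone H2A gene, 1.3 ± 0.23. C2orf68 (1.27 ± 0.36), the RING finger gene RNF122 (1.24 ± 0.64) and the iron-sulfur assembly gene NUBP1 (1.23 ± 0.37) completed the set. All 15 were above 0 in 4 of 4 immunoprecipitations, with limma adjusted p from 0.0116 to 0.0185. Surrogates made up 50% of the spots at ZNF678, 40% at ZNF33B and 33.3% at H2AC15, and with normexp background correction these promoters fell under the size limit.

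**Figure D1:**
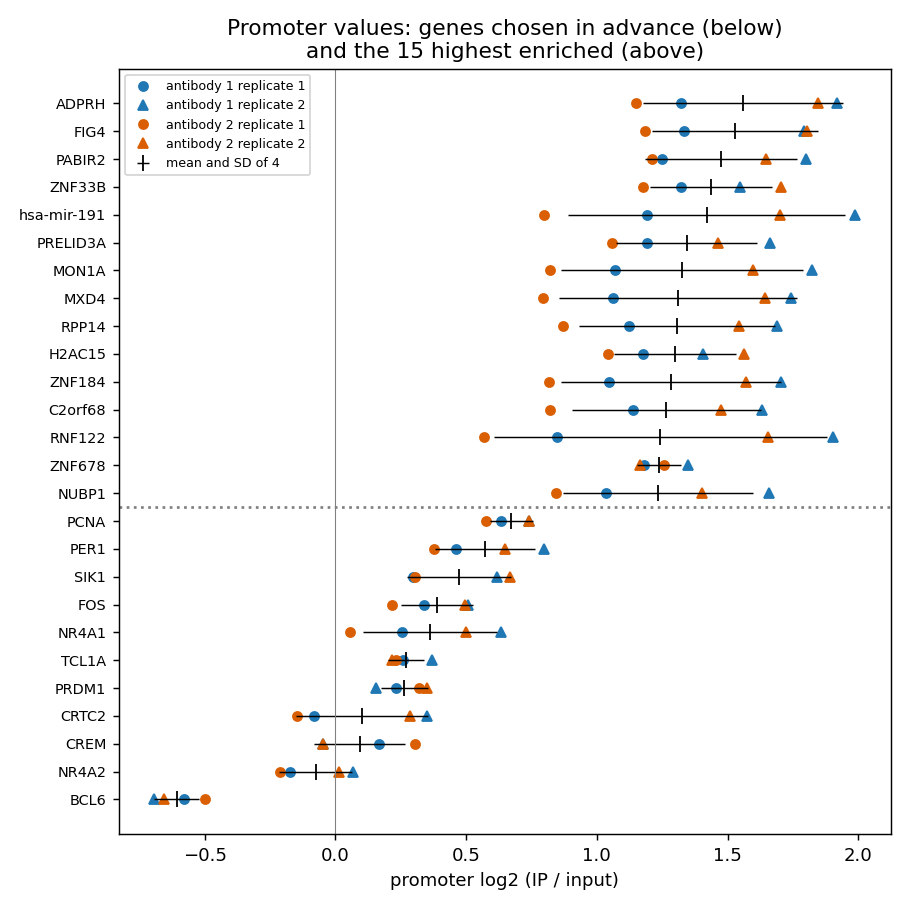
Promoter log2 ratio of immunoprecipitate over input (horizontal axis) for 11 genes chosen in advance (below the dotted line) and the 15 highest enriched genes (above it). Symbols are the 4 immunoprecipitations and black bars the mean and SD of 4. PCNA lies at 0.67 and BCL6 at −0.61, and the highest gene, ADPRH, at 1.56.

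Of the 12 genes chosen in advance, 11 are given here. PCNA, the sliding clamp of DNA replication, was enriched at 0.67 ± 0.08 (adjusted p = 0.0135), though with probes carrying a surrogate left out, or with normexp, its value was under the limit. The call on PCNA was lost in 5 of 23 alternatives, and its lowest value over all of them was 0.43. BCL6, the repressor that maintains germinal centre B cells, was depleted at −0.61 ± 0.09 (adjusted p = 0.0145). That call on the promoter of BCL6 was lost in 10 of 23 alternatives, among them normexp (−0.26), the probe-length correction (−0.44), loess (−0.47) and run 1 alone (−0.54). It was lost without antibody 1 replicate 2 (−0.58) and without antibody 2 replicate 2 (−0.57). The CREB targets PER1, a clock gene (0.57, adjusted p = 0.0188), SIK1, a kinase that restrains CRTC2 (0.47, adjusted p = 0.0292), and FOS (0.39, adjusted p = 0.0344) passed the p limit but not the size limit. NR4A1 (0.36), TCL1A, a B cell oncogene (0.27), PRDM1, the plasma cell regulator (0.26), CRTC2 itself (0.10), CREM (0.09) and NR4A2 (−0.08) were not called. Surrogates made up 62.5% of the spots at PRDM1 and 50% at CREM, and with normexp the promoter of PRDM1 was at −0.19 and the promoter of CREM at −0.20.

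CREB and CRTC target genes had 8 of 36 members enriched, 2 depleted and 26 not called. Enriched were the phosphatase gene DUSP1 (0.89 ± 0.33), the clock gene PER2 (0.86 ± 0.44), the coactivator gene CITED2 (0.84 ± 0.49) and the AP-1 gene FOSB (0.75 ± 0.23). The depleted members were G6PC1, of gluconeogenesis (−1.06), and SST, the hormone somatostatin (−1.11). Of 24 cAMP and CRTC2 pathway genes, 3 were enriched and 0 depleted by limma, with 0 below 0 at an unadjusted p under 0.05. These were CRTC1, a paralogue of CRTC2 (0.81 ± 0.43), the calcineurin subunit gene PPP3CA (0.77 ± 0.53) and STK11, the kinase upstream of the SIK family (0.73 ± 0.37). Neither list shifted against the other promoters by camera (adjusted p = 0.505 and 0.212).

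Of 29 germinal centre B cell genes, 3 were enriched and 2 depleted, and adjusted over the list alone the enriched count was 2. CD40, the receptor for T cell help, stood at 0.86 ± 0.30 and BACH2, a repressor of plasma cell fate, at 0.62 ± 0.47. The call on the promoter of BACH2 was lost in 12 of 23 alternatives, with 0.44 without antibody 1 replicate 2 and 0.40 without antibody 2 replicate 2. RGS13, a regulator of G protein signalling, was called at 0.71 ± 0.24, but 100% of its spots held a surrogate, so the value is an upper limit and not a measured enrichment. MS4A1, which encodes CD20, was depleted with BCL6 (−0.89). Of 18 plasma cell genes, 5 were enriched and 0 depleted by limma, with 1 below 0 at an unadjusted p under 0.05. The enriched ones included the translocon gene SSR4 (0.77 ± 0.45), the transcription factor gene IRF4 (0.71 ± 0.50) and MZB1, a chaperone of antibody assembly (0.66 ± 0.24). JCHAIN, the joining chain of antibodies, was called at 0.75 ± 0.34 with 90% of its spots on surrogates. With normexp the promoter of RGS13 was at −0.61 and the promoter of JCHAIN at −0.45. Camera gave an adjusted p of 0.374 for both lists.

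DNA repair and damage response genes had 5 of 29 members enriched and 1, the checkpoint kinase gene ATR (−0.61), depleted. The uracil glycosylase gene UNG stood at 0.90 ± 0.30 and the mismatch repair gene MSH6 at 0.74 ± 0.42. Of 31 cell cycle genes, 7 were enriched and 0 depleted by limma, with 0 below 0 at an unadjusted p under 0.05. The enriched ones were led by the cyclin genes CCND3 (0.86 ± 0.34) and CCNE2 (0.73 ± 0.43), the topoisomerase gene TOP2A (0.79 ± 0.36) and the checkpoint gene MAD2L1 (0.74 ± 0.09). Replication dependent histone genes had 13 of 48 members enriched, including H2AC17 (1.16 ± 0.19), H4C9 (1.06 ± 0.18) and H2AC8 (0.98 ± 0.12), and 5 depleted. Fry found the histone list above 0 (adjusted p = 0.0217), whereas camera found no shift against other promoters (adjusted p = 0.505). The histone list's shift was 0.10 over all samples, and camera with the replicate block gave an adjusted p of 0.853. It was 0.16 in run 1 alone, where camera called it (adjusted p = 0.0127), and 0.05 in run 2 alone. Over all samples an estimated correlation gave an adjusted p of 0.960. Under normexp the shift was −0.36, and surrogates made up 37.5% of the spots of histone promoters. Camera adjusted p was 0.840 for DNA repair and 0.148 for cell cycle genes.

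Of 75 mitochondrial respiratory chain genes, 16 were enriched and 2 depleted, with the ATP synthase genes ATP5F1C (0.96 ± 0.27) and ATP5F1D (0.80 ± 0.33), the complex III gene UQCRC1 (0.85 ± 0.31) and the complex I gene NDUFS3 (0.75 ± 0.22) highest. Of 72 cytosolic ribosomal protein genes, 8 were enriched and 2 depleted, among the enriched RPS7 (0.72 ± 0.36), RPL11 (0.69 ± 0.24), RPS15A (0.67 ± 0.13) and RPS20 (0.62 ± 0.16). Their camera adjusted p values were 0.374 and 0.505. With narrower promoters the ribosomal list was called at a shift of 0.16 (adjusted p = 0.0149), whereas over the promoters of 1 kb an estimated correlation gave 0.960.

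Genes of other cell types gave the comparison for these lists. Of 16 hepatocyte marker genes, 5 were depleted and 0 enriched by limma, with 0 above 0 at an unadjusted p under 0.05. The depleted members included TTR, the thyroid hormone carrier (−1.41 ± 0.52), and CYP3A4, a drug-metabolising enzyme (−1.32 ± 0.33), and the highest member was SERPINA1 at 0.29, not called. The hepatocyte list lay below the other promoters by camera (adjusted p = 0.00019), and so did the olfactory receptor genes (adjusted p = 3.66e-44). With an estimated correlation neither call held (adjusted p = 0.960 for both). Fry called neither (adjusted p = 0.117 for both). With the replicate block the camera adjusted p was 0.0025 for hepatocyte and 1.34e-41 for olfactory receptor genes. The hepatocyte shift was −0.68, against −0.36 in run 1, −0.89 in run 2 and −0.28 with the probe-length correction. For olfactory receptor genes the shift was −0.90, against −0.58 in run 1, −1.22 in run 2 and −0.43 with that correction. The sole enriched olfactory gene was OR13J1 (0.64 ± 0.40). That call on the promoter of OR13J1 was lost in 12 of 23 alternatives, among them run 1 alone (0.30), and it was at 0.47 without antibody 1 replicate 2 and without antibody 2 replicate 2. Adjusted over the list alone 155 were depleted. Surrogates made up 41.9% of the spots of olfactory promoters and 35.9% of those of hepatocyte genes, so these depletions are partly upper limits.

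T cell marker genes had 1 of 17 enriched, the transcription factor gene TBX21 (0.59 ± 0.40), and 3 depleted, among them CD3G of the T cell receptor complex (−1.32 ± 0.42). Their median was 0.13, their mean −0.06 and the test pointed down (camera adjusted p = 0.275). Of 15 neuron marker genes, 1 was enriched, the neurofilament gene NEFL (0.59 ± 0.34). Both calls were lost in 12 of 23 alternatives. In run 1 alone the promoter of TBX21 was at 0.26 and the promoter of NEFL at 0.30. They were at 0.45 and 0.46 without antibody 1 replicate 2, and at 0.40 and 0.43 without antibody 2 replicate 2. Of 16 skeletal muscle marker genes 0 were called by limma, with 5 above and 2 below 0 at an unadjusted p under 0.05, and the desmin gene DES was highest at 0.55. Camera adjusted p was 0.767 for the neuron and 0.911 for the muscle list. Except where a value is given, enriched and depleted counts adjusted over the list alone equalled those over all genes. The depleted members named beside the lists, other than BCL6, were chosen after their values were seen.

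**Figure D2:**
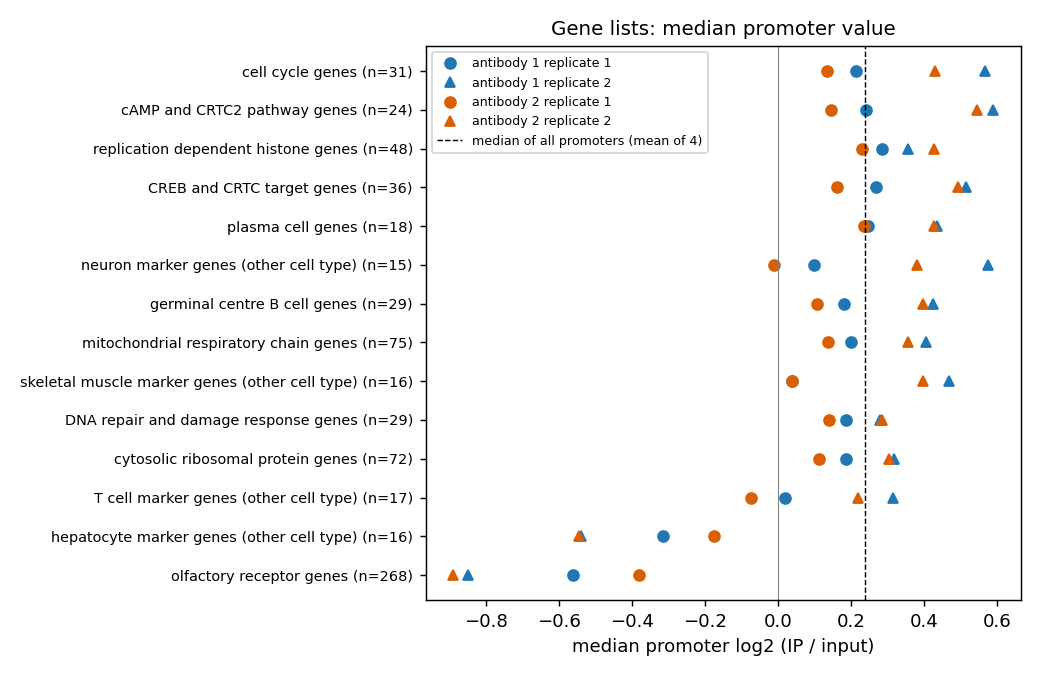
Median promoter log2 ratio of immunoprecipitate over input (horizontal axis) for the 14 gene lists (vertical axis, n is the number of members). Symbols are the 4 immunoprecipitations, the dashed line is the median of all promoters, 0.24, and the hepatocyte and olfactory receptor lists are the only ones with all 4 medians below 0.

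Along the genome, 47670 of 397866 windows (12.0%) were enriched and 80829 (20.3%) depleted. Within 1 kb of a gene start 20.1% of 135250 windows were enriched and 10.1% depleted, against 7.32% and 26.1% of 247858 windows farther away. In the 250 bp after the start the mean log2 ratio was 0.19 and 0.54 in the replicates of antibody 1, and 0.11 and 0.48 in those of antibody 2. Probes there were shorter, 47.8 bp against 55.3 bp between −5000 and −4750 bp. By the array annotation, 18.5% of windows in divergent promoters were enriched and 14.7% depleted. Inside genes the shares were 13.3% and 17.3%, in other promoters 10.3% and 23.7%, and downstream 6.74% and 27.1%. With single windows left out, enriched windows formed 10114 regions with a median of 4 windows and a median length of 499 bp. The highest were at ADPRH (1.51 ± 0.50), the cell cycle factor gene E2F2 (1.49 ± 0.48), ZNF33B (1.48 ± 0.38), the granzyme inhibitor gene SERPINB9 (1.43 ± 0.27) and MXD4 (1.37 ± 0.42). The E2F2 region spanned 23600172 to 23600710 on chromosome 1, and that at SERPINB9 spanned 2847259 to 2847702 on chromosome 6. Surrogates made up 9.43% of spots in enriched windows and 47.3% in depleted ones. In the highest regions the share was 33.3% at ADPRH, 33.3% at SERPINB9, 25% at ZNF33B, 16.7% at E2F2 and 0% at MXD4.

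**Figure D3:**
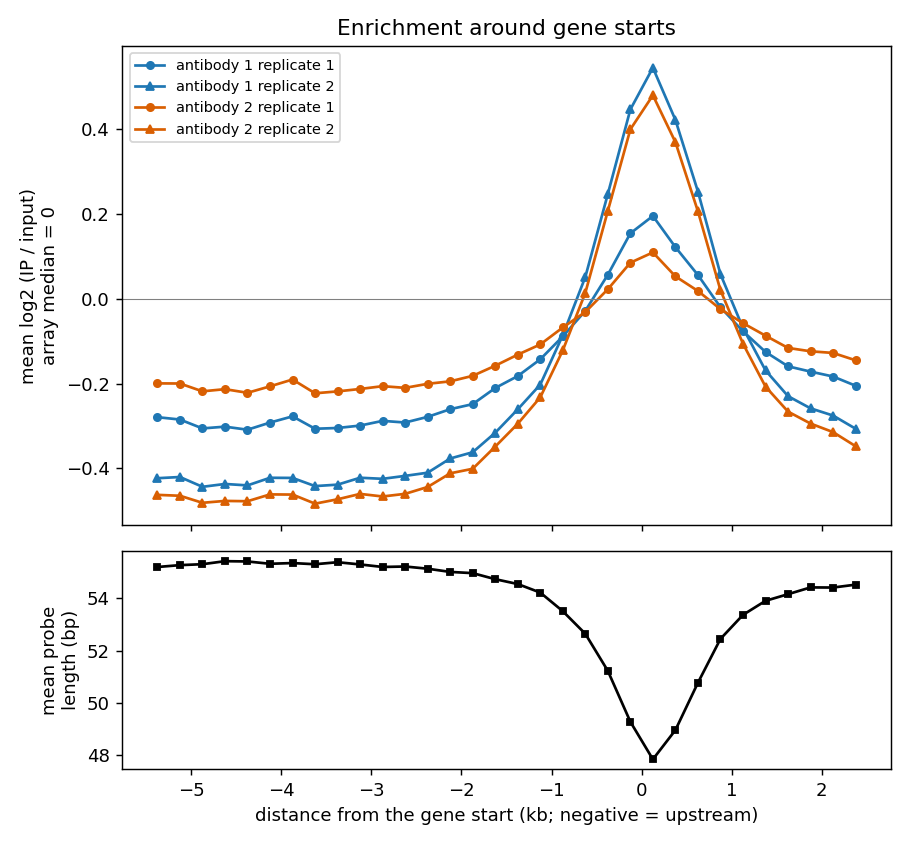
Mean log2 ratio of immunoprecipitate over input per 250 bp bin (upper axis) and mean probe length in bp (lower axis) against distance from the gene start in kb, with negative values upstream. Lines are the 4 immunoprecipitations, which peak in the first bin after the start, between 0.11 and 0.54, where probes are shortest.

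Of the 2457 enriched promoters, 1123 held no surrogate spot, and 2 consisted of surrogates alone. The enriched count was 2504 with the replicate block, 675 in run 1 alone and 5450 in run 2 alone, and for windows it was 49030, 19969 and 93806. Depleted promoters numbered 1250, 886 and 1728, and depleted windows 82101, 59302 and 106943. The blocked counts leave the run difference out of the error. Of 62 genes named by the rule against input, 51 were called and so could lose a call. In run 1 alone 24 of the 51 lost it, among them PER2, CITED2, BACH2, IRF4, CRTC1, STK11, TOP2A and BCL6. DUSP1, CD40 and UNG kept theirs. Without antibody 1 replicate 2, 13 lost their call, and without antibody 2 replicate 2, 14. Of the 51, 24 lost their call when centred on the median promoter and 20 with the probe-length correction. The 2-fold limit cost 34 their call, and an adjusted p under 0.01 cost all 51 theirs. Leaving out surrogates cost 17 their call, with 58 of the 62 named genes still measured. The calls on MZB1 and PPP3CA were lost in 10 of 23 alternatives. With the probe-length correction, 1292 promoters were enriched and 628 depleted, and 860 of the enriched were among the 2457.

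The second comparison, antibody 1 against antibody 2, asks whether the antibodies to different parts of CRTC2 gave different profiles. By limma 0 promoters and 0 windows differed, with 0 promoters and 3 windows at an unadjusted p under 0.05. That fit counts the run difference shared by both antibodies as error, so these low counts do not show that the antibodies agree. With the replicate block the counts called were again 0, with 1793 of 16540 promoters and 22479 of 397866 windows at an unadjusted p under 0.05. Without any difference a share near 0.05 falls under that limit, which the blocked promoters exceed. In the simulation of the mean against input, the block put 6.70% of unchanged genes under it. The median difference over all promoters was 0.051, with a median blocked standard error of 0.059. Such a shared offset can raise the share, so the excess does not show differences at single genes. With the probe-length correction and the block, 15807 windows were under the limit. The smallest p with antibody 1 higher belonged to TMED9, of vesicle transport (difference 0.34), ZNF789 (0.36), the cytotoxic granule gene GNLY (0.39), MECR of mitochondrial fatty acid synthesis (0.40) and CCDC138 (0.34). Those with antibody 2 higher were SERPINB10 (−0.32), BHMT2 (−0.31), the myosin gene MYO16 (−0.30), DMBX1 (−0.27) and the sphingomyelin synthase gene SGMS2 (−0.26). None of these 10 differences was called, and each had an adjusted p of 1.00. Surrogates made up 60% of the spots at SERPINB10 and 47.2% at MYO16. Leaving out 1 immunoprecipitation kept the sign of each difference but moved its size. MECR ranged from 0.15 to 0.65, GNLY from 0.22 to 0.57 and BHMT2 from −0.44 to −0.19. The counts and differences above take antibody and replicate from the sample titles, which the deposited z scores did not match. The z columns named for 1 antibody correlated with each other at 0.963 (antibody 1) and 0.988 (antibody 2), and those of different antibodies at 0.846 to 0.905. Each array set gave 24 one-to-one pairings of columns with arrays. Over windows, in both sets the best exchanged antibody 1 replicate 2 with antibody 2 replicate 1, at a mean correlation of 0.947 and 0.971, against 0.852 and 0.899 by the titles. Over probes the same pairing was best in both sets (0.643 and 0.681, against 0.582 and 0.632). With those labels exchanged, 2581 promoters and 99509 windows differed, and antibody and run then coincide.

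Taken singly, antibody 1 had 17191 enriched and 53255 depleted windows, and antibody 2 had 5100 and 38889. Which antibody had more enriched windows depended on single immunoprecipitations. Without antibody 1 replicate 2 the enriched counts were 164 and 22372, and without antibody 2 replicate 1 they were 58747 and 59020. Without antibody 1 replicate 1 they were 33732 and 22372, and without antibody 2 replicate 2 they were 58747 and 2076. For either antibody alone 0 promoters were called by limma, with 7038 and 5468 at an unadjusted p under 0.05. With the replicate block, however, 3135 and 1937 were enriched and 1301 and 1215 depleted. The block takes the run difference out of the error, so the blocked counts do not show agreement between replicates. Windows enriched with the block numbered 58745 and 40076, and windows depleted with it 85416 and 79153. The median difference between antibodies was 0.05 and 95% of promoters differed by less than 0.18 in either direction. The 95% interval of a difference extended a median of 0.60 to either side, or 0.14 with the block, so differences within it were not detectable.

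Arrays resembled each other by run more than by antibody. Across genes, which are not independent replicates, promoter values of different antibodies correlated at 0.943 in run 1 and 0.988 in run 2. The replicates of antibody 1 correlated at 0.874 and those of antibody 2 at 0.752. The median difference between runs, regardless of sign, was 0.34, against 0.07 between antibodies. Antibody is again as titled here. Grouped by the best pairing with the z columns, the 2 arrays of a run would belong to 1 antibody.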

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

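The test of each gene list's difference between antibodies was chosen after the data were seen and was run on all 14 lists.

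In 3 lists camera found a difference between antibody 1 and antibody 2 at the preset correlation. The median of antibody 1 minus antibody 2 was −0.0122 for replication dependent histone genes, with medians of 0.31 and 0.34 (adjusted p = 0.00221, and 0.681 with an estimated correlation). It was −0.0537 for hepatocyte marker genes, with medians of −0.50 and −0.38 (adjusted p = 0.00595, and 0.968 with an estimated correlation). For olfactory receptor genes it was −0.0456, with medians of −0.70 and −0.64 (adjusted p = 3.95e-15, and 0.968 with an estimated correlation). With the replicate block the adjusted p at the preset correlation was 0.00133, 0.00381 and 7.77e-17. Over all promoters the median difference was 0.05. The calls rest on the preset correlation, since none of the 3 held with an estimated one, and on the antibody labels of the sample titles.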

How the results depend on the processing

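Leaving out probes with a surrogate, the LogRatio column, the probe-length correction, centring on the median promoter, single runs, leaving out X and Y and exchanged labels were tests chosen after the data were seen; the others were fixed in advance. The cause was not tested for any change below unless stated. No window or promoter differed between antibodies by limma in any alternative that kept the titles' labels, with 0 to 22479 windows at an unadjusted p under 0.05. With the labels exchanged as the z columns pair, 99509 windows and 2581 promoters differed and antibody 2 had 93806 enriched windows, by construction those of run 2. The antibody difference then changed sign at TMED9 (−0.10), ZNF789 (−0.22), GNLY (−0.33), MECR (−0.29), SERPINB10 (0.14), BHMT2 (0.24), MYO16 (0.14), DMBX1 (0.048) and SGMS2 (0.057).

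The 47670 enriched windows, 17191 of antibody 1, 5100 of antibody 2 and 2457 promoters became 100525, 109310, 85495 and 5438 with normexp. With loess the antibody counts were 28969 and 14729, with equal spread 42846 and 34377, with the block 58745 and 40076, with LogRatio 31855 and 10770, and with the length correction 40754 and 36932 (42094 and 38473 with the block). No filter on dim probes gave 11544 for antibody 2. Single probes gave 94321, 52020 and 30064 windows. No size limit gave 78055 windows and 5349 promoters, by construction more, and the 2-fold limit 4207, 5530, 1582 and 108. At an adjusted p under 0.01, 10974 windows of both antibodies were left and 0 by limma for antibody 1, antibody 2 and promoters (168226, 141889 and 9654 at an unadjusted p under 0.05). Leaving out surrogates gave 15089 windows and 929 promoters. Run 1 gave 19969 and 675, run 2 93806 and 5450. Promoters numbered 3972 when narrower, 1292 with the length correction, 532 when centred on the median promoter, and 6792 and 804 at a mean z of at least 1 and 2. Leaving out 1 immunoprecipitation, the lone one left being assumed to vary like the others, gave 29159 (without antibody 2 replicate 2) to 73337 (without antibody 2 replicate 1) windows and 1252 to 4075 promoters for the same 2. Antibody 1 windows ranged from 164 (without antibody 1 replicate 2) to 58747 (without antibody 2 replicate 1), and antibody 2 windows from 2076 (without antibody 2 replicate 2) to 59020 (without antibody 2 replicate 1). Antibody 2 had more windows than antibody 1 without antibody 1 replicate 2, without antibody 2 replicate 1 and with the labels exchanged. Depleted windows of both antibodies, 80829 in number, ranged from 26664 without surrogates to 119098 with single probes, and outnumbered enriched windows in every alternative except normexp (97597 against 100525). The number of called lists was 2 in each fit without 1 immunoprecipitation, 3 with the length correction (also with the block), in run 1 and when narrower (ribosomal genes being the third there), 0 with an estimated correlation and 1 (histone) with fry.

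The enriched share of promoter calls was 66.5%, and it was 79.5% with normexp, 79.8% with loess, 78.7% when narrower, 50.3% without surrogates, 43.2% in run 1 and 20.4% centred on the median promoter. The median promoter, 0.24, was 0.38 with normexp, 0.35 when narrower, and 0.13 without surrogates and with the length correction. Hepatocyte and olfactory shifts stayed below 0 and called in 18 of 18 alternatives of processing and samples, from −0.89 and −1.22 in run 2 to −0.28 and −0.43 with the length correction. Neither was called with an estimated correlation (adjusted p = 0.960) or by fry (0.117). The histone shift was called at 0.26 with the length correction (adjusted p = 0.0387), but not over all samples with an estimated correlation (0.960).

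Other values changed sign. With normexp the shift of CREB and CRTC target genes was −0.0027 and of replication dependent histone genes −0.36. The promoter of RGS13 was at −0.61, the promoter of JCHAIN at −0.45, the promoter of CREM at −0.20, the promoter of PRDM1 at −0.19 and the promoter of NR4A2 at 0.27. With loess, ribosomal genes were at 0.020, neuron genes at −0.026, muscle genes at 0.011 and NR4A2 at 0.034. With equal spread, DNA repair genes were at 0.0041 and ribosomal genes at 0.0039. With no dim filter, DNA repair was at 0.12, ribosomal at 0.048, respiratory at −0.00075 and muscle at 0.0034. When narrower, DNA repair was at 0.096, ribosomal at 0.16, histone at −0.094, NR4A2 at 0.48 and PRDM1 at −0.13. Without surrogates, ribosomal genes were at 0.039 and neuron genes at −0.053. With LogRatio, histone genes were at −0.031, muscle genes at 0.027, CREM at −0.0011 and PRDM1 at −0.057. With the length correction, also with the block, DNA repair was at 0.089, ribosomal at 0.083, neuron at −0.054 and the promoter of CRTC2 at −0.0033. Centred on the median promoter, CREM was at −0.15 and CRTC2 at −0.14. In run 1, DNA repair was at 0.057, ribosomal at 0.062, neuron at −0.051 and CRTC2 at −0.11. In run 2, muscle was at 0.061, CREM at −0.049 and NR4A2 at 0.041. Muscle was at 0.00040 without X and Y. Leaving out 1 immunoprecipitation, DNA repair ranged from −0.065 to 0.037, ribosomal from −0.045 to 0.045, neuron from −0.038 to 0.14, muscle from −0.049 to 0.022 and CRTC2 from −0.0065 to 0.21. Of the promoters whose value changed sign, RGS13 and JCHAIN had been called against input. Of the lists, ribosomal genes were called by camera when narrower, and histone genes by fry, and by camera in run 1 and with the length correction.

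Signal over background limits the values: at promoters where all spots held a surrogate, 58 in number, a ratio is only an upper limit. The correction for GC content and the search for the CRE motif were not run, for want of probe sequences and a genome.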

Other observations

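Chosen after the result was seen were the tests of a shared difference between runs, of the input channel, of surrogates in the run difference, of exchanged labels and of binding at gene starts, and the values in the first 2 paragraphs; the tests of probe length, of surrogates at gene starts and of chromosome X were set beforehand.

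Within the histone list, 5 genes were depleted while 13 were enriched. The lowest were H2BC1 (−0.99 ± 0.20) and H2AC1 (−0.86 ± 0.12), known as testis variants of histones H2B and H2A. H4C7 (−0.76 ± 0.16), H3C6 (−0.75 ± 0.25) and the linker histone gene H1-1 (−0.62 ± 0.16) followed. In the respiratory chain list the depleted genes were NDUFB5 (−1.24 ± 0.26) and NDUFA5 (−0.59 ± 0.20), both of complex I. In the ribosomal list they were RPL4 (−0.66 ± 0.12) and RPL23A (−0.61 ± 0.19).

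The deposited z scores, averaged per promoter, correlated with the promoter values at a Pearson r of 0.955 and a Spearman rho of 0.942 across genes. A mean z of at least 2 was reached by 804 promoters, of which 762 were among the 2457 enriched. Both lists come from the same immunoprecipitations, so this overlap is no independent support. Over windows, the first column named for antibody 1 correlated best with antibody 1 replicate 1 (0.956), and so did the second (0.931). The first column named for antibody 2 correlated best with antibody 1 replicate 2 (0.983), and the second with antibody 2 replicate 2 (0.983). Over single probes, however, both columns named for antibody 1 correlated best with antibody 2 replicate 2, a run 2 array (0.660 and 0.622, against 0.626 and 0.610 for antibody 1 replicate 1). Taken singly, the columns named for antibody 1 therefore do not settle which run they follow. Those named for antibody 2 correlated best with run 2 arrays over probes as well (0.716 and 0.723, against 0.552 and 0.554 for antibody 1 replicate 1). Which array fed which column is not stated.

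Ratios were higher within 250 bp of gene starts than in the upstream flank, by a mean log2 difference of 0.66 (0.31 to 0.93 over the 4 immunoprecipitations). The flank was 5000 to 3000 bp upstream, and downstream probes were not part of it. Base composition of each probe, with probe length as proxy, is not the whole source among probes of 46 to 59 bp. At equal length a difference of 0.42 (0.29 to 0.53) was left there. That is 63.7% (54.9% to 94.0%) of the difference over all probes, of 45 to 60 bp, so this share compares 2 probe sets. Surrogates are not the whole source either, since 74.2% (72.2% to 83.4%) was left without probes carrying them. Composition of the region may contribute, since windows at equal mean probe length kept 35.6% (27.3% to 63.5%), which lies between the bounds set for and against it. Binding of CRTC2 at gene starts stays open as well, since no mock immunoprecipitation was among the samples to set beside the 0.66. The last 2 cannot be told apart here.

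Arrays resembled each other by run rather than by antibody, and the 0.936 at which the antibodies' replicate differences correlated over promoters restates that and decides nothing about its source. Between runs the input signal correlated less than the immunoprecipitate signal in 4 of 4 antibody and set pairs (0.874 to 0.930 against 0.965 to 0.985), but within runs it did so in 4 of 4 pairs too (0.960 to 0.986 against 0.985 to 0.997), so whether the difference lies in the input channel stays open. Surrogates are argued against, since without them the lowest correlation within a run still exceeded the highest within an antibody by 0.0968. Exchanged labels of antibody 1 replicate 2 and antibody 2 replicate 1 are a candidate explanation for its not following antibody, since z columns and arrays paired better that way, by a mean correlation of 0.0835 (0.0726 and 0.0944 in the 2 sets), although the second column of antibody 1 taken singly correlated better with antibody 1 replicate 1. Whether the arrays or the columns carry the exchanged labels stays open, and so does a biological difference between the replicate cultures, which was not tested. Ratios correlated with probe length at −0.31 and −0.19 in run 1 (antibody 1 and 2) and at −0.55 and −0.53 in run 2. With the length correction, enriched promoters without and with the block were 1400 and 1415 for antibody 1, and 1184 and 1201 for antibody 2. Uncorrected they were 0 and 3135, and 0 and 1937. The run difference therefore went in part with probe length. That comparison was made after the result was seen, and its cause was not tested.

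Ratios on chromosome X exceeded those on the autosomes by 0.28 ± 0.01 (SD, n = 4), and the input signal there was lower by a log2 difference of −0.73 ± 0.26. The lower input is argued against as the whole source, since 80.8% (72.8% to 88.2%) of the difference was left at equal input and probe length. Matching on the input of the other run left 93.0% (51.8% to 136%). Probe length alone is argued against too, since 124% (109% to 137%) was left at equal length. No biological explanation was tested, since the design holds none.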
